A study of Rattus norvegicus with 49 samples.

How the data were processed

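Total RNA of liver and kidney was hybridized to Affymetrix Rat Genome 230 2.0 arrays, 1 array per tissue sample, per the labels' protocols. The deposited values are log2 expression values per probe set, summarised with RMA per the submitters' processing notes. The log2 scale was read from the range of the values. The version of RMA is not given in the sources used here, nor whether liver and kidney arrays were normalized together. Levels are therefore compared within an organ, and the organs are compared only through their changes from their own controls. RMA includes background correction and a normalization that equalizes array distributions, which can hide a change shared by most genes. No detection calls were used, so low values hold an unknown share of background.

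The table held 31099 probe sets. Of these, 57 were control probe sets, 20826 had 1 gene symbol, 436 had several and 9780 had none. Symbols were looked up through the Entrez identifiers of the platform annotation for 20758 probe sets and through accessions for 2, and 66 kept the symbol given. The symbol differed from that of the platform annotation for 1 probe set. Each gene was represented by the probe set with the highest mean over the 49 arrays, which gave 14217 genes, 4525 of them with several probe sets. Probe sets with no symbol or several were not named.

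Groups were taken from the sample titles. The text of the series gives 4 samples for each dose group with compound, and 3 kidney samples at 500 mg/kg were analysed here. The labels call the samples biological replicates. For each organ a linear model with 1 mean per dose group was fitted to all arrays with limma 3.58.1 in R 4.3.3, and contrasts against 0 mg/kg and between 1000 and 500 mg/kg were tested with empirical Bayes moderation. A separate model tested the trend with dose rank. The difference between the organs' responses at 1000 mg/kg was a contrast in a model over all 49 arrays. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Of 43 gene lists, those with at least 5 measured genes were tested, 34 in liver and 38 in kidney, with camera at a preset correlation of 0.01. Their p-values were adjusted over lists and doses within an organ. Camera with an estimated correlation and fry were alternatives. Lists, tests and alternatives were fixed before the data were examined, except where stated.

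The genes named were chosen by rule. At 1000 mg/kg these were the 10 largest rises and 10 largest falls in each organ among called genes whose arrays did not overlap those of the controls, and at 500 mg/kg the 5 largest each way. At 1, 10 and 100 mg/kg they were up to 5 called genes with the smallest adjusted p. For 1000 against 500 mg/kg and for the comparison of organs they were the 5 largest each way. For each list described they were up to 4 members with the smallest p at 1000 mg/kg. Symbols starting with LOC, RGD, MGC or AABR were passed over. Genes called in both organs, neighbours of Gstt3 and single members of lists outside this rule were chosen after their values were seen.

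The alternatives were the mean of all probe sets of a gene, genes at or above the median mean level only, quantile normalization within the organ, arrays centred on their median, a variance trend with robust moderation, array weights, the replicate number as a block, a fit of the 2 groups alone, and leaving out each array in turn. After the data were seen, the kidney was also fitted with the mean adipocyte marker level as a covariate and without arrays more than 0.5 log2 units above the control mean of these markers, and the organs were compared with dose and replicate number as a random block. Whether other splits of the arrays gave counts as large was tested with at most 100 splits per result.

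The models were tested on simulated data drawn from the gene means and residual spread of each organ, with 200 of 14217 genes changed at 1000 mg/kg. In liver 72% of genes changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 3-fold or 4-fold were called, and in kidney 84%, 100%, 100% and 100%. Of the 14017 unchanged genes 16 were called in each organ. The noise was drawn independently for each gene and array, without effects shared by genes or arrays. These rates hold for such noise only.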

Results

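Gene expression was measured in the liver and kidney of male Harlan Sprague Dawley rats, an outbred laboratory stock, given propylene glycol phenyl ether by gavage for 5 consecutive days. This glycol ether is used as a solvent. The vehicle was corn oil at a dosing volume of 5 mL/kg. Tissues came from groups given 0, 1, 10, 100, 500 or 1000 mg/kg, and no tissue was collected at 2000 mg/kg. Each of the 49 arrays holds RNA of 1 tissue sample. The 25 liver arrays comprise 5 at 0 mg/kg and 4 at each dose with compound. The 24 kidney arrays comprise 5 at 0 mg/kg, 3 at 500 mg/kg and 4 at each of the other doses. The treatment text of the labels names a different compound (MCHM) from the series title and sample labels, and the latter are followed here. Expression of 14217 genes was analysed on the log2 scale. Array medians lay between 6.47 and 6.62 in liver and between 6.62 and 6.77 in kidney, and pairs of arrays of an organ correlated at 0.987 or more across genes. The number of arrays limits the precision of every value. All adjusted p-values for genes are from limma with Benjamini-Hochberg adjustment over 14217 genes.

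At doses of 1 to 100 mg/kg the liver showed 1 called gene. Gstt3, a theta class glutathione transferase, was 2.06-fold higher at 10 mg/kg, at 10.10 ± 0.27 (SD, n = 4) against 9.06 ± 0.20 (SD, n = 5) in controls (limma adjusted p = 0.0104). All 4 arrays lay above every control array. The count was 0 without control replicate 4 or 10 mg/kg replicate 1 or 3, 2 without control replicate 1 or 10 mg/kg replicate 4, and 0 in a fit of the 2 groups alone (Gstt3 adjusted p = 0.244). No gene passed at 1 or 100 mg/kg with limma. Unadjusted p-values under 0.05 numbered 1344 at 1 mg/kg, 1311 at 10 mg/kg and 1305 at 100 mg/kg, which is 9.45%, 9.22% and 9.18% of the genes. A limma fit of the 2 groups alone called 0 genes at 1 mg/kg and 1 gene at 100 mg/kg.

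At 500 mg/kg, 7 liver genes were higher than in controls and 0 were lower. Gstt3 rose 2.42-fold, to 10.34 ± 0.22 (SD, n = 4), with a limma adjusted p of 0.000379. Nqo1, a quinone reductase, rose 1.88-fold from 7.29 ± 0.27 to 8.20 ± 0.13 (adjusted p = 0.00251). Mif, a cytokine, rose by 0.64 on the log2 scale, Pex19, a peroxisome assembly factor, by 0.41, and Samm50, of the mitochondrial outer membrane, by 0.40. Their adjusted p-values were 0.0219, 0.0262 and 0.0482. The count was sensitive to the analysis: 67 genes passed when only the brighter genes were tested, 53 with a variance trend and 1 in a fit of the 2 groups alone. The count was 2 without control replicate 1, 4 without control replicate 3, 2 without 500 mg/kg replicate 1 or 3, and 14 without 500 mg/kg replicate 2.

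**Figure D1:**
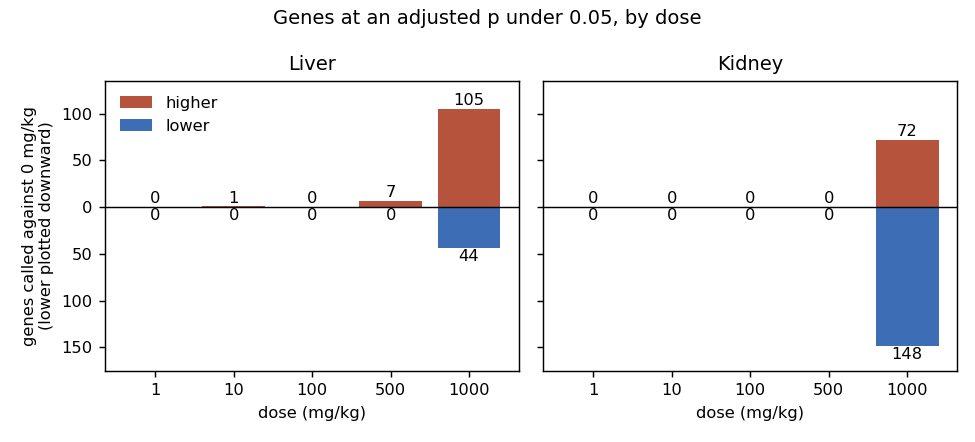
Number of genes at an adjusted p under 0.05 against 0 mg/kg (y axis, higher genes upward and lower genes downward) by dose in mg/kg (x axis), for liver and kidney. The counts at 1000 mg/kg were 105 higher and 44 lower in liver, and 72 higher and 148 lower in kidney.

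The highest dose with tissue, 1000 mg/kg, changed 149 genes in liver. Gsta3, a glutathione transferase, had the largest rise among the named genes, 6.27-fold from 6.77 ± 0.84 (SD, n = 5) to 9.42 ± 0.22 (SD, n = 4), with a limma adjusted p of 9.13e-05. Gstt3 rose 3.69-fold to 10.94 ± 0.17 (adjusted p = 2.69e-07), and Abcc3, an organic anion exporter, 3.41-fold from 5.39 ± 0.47 to 7.16 ± 0.38 (adjusted p = 9.01e-06). Nqo1 rose 2.51-fold to 8.62 ± 0.15. Further rises were 2.83-fold for Adh7, an alcohol dehydrogenase, and on the log2 scale 1.43 for Acsm2, 1.28 for Ces2c, a carboxylesterase, 1.26 for Akr7a3, an aldo-keto reductase, 1.21 for Cidea, a lipid droplet protein, and 1.14 for Acat2. The largest falls among the named genes were in Cdkn3, from 6.14 ± 0.75 to 3.98 ± 0.24, and Cdk1, the mitotic cyclin-dependent kinase, from 6.10 ± 0.23 to 4.13 ± 0.30. These were changes of -2.16 (adjusted p = 0.0375) and -1.98 (adjusted p = 0.00625) on the log2 scale. Ccnd1, cyclin D1, changed by -1.62, Aldh1b1 by -1.30, Nrcam by -1.06, Apoa4, an apolipoprotein, by -1.05, Nrep by -1.03, Slpi by -0.90, Slc34a2 by -0.82 and Klrg1 by -0.75. At 1000 mg/kg the levels of Cdkn3, Cdk1 and Nrcam (3.96) are not shown to lie above background. The sizes of these 3 falls, and so their rank, are not settled. Ccnd1 and Nrcam, and Fdft1, Igfbp3, Igf1 and Ghr below, have other probe sets. Among results from other probe sets of named genes in either organ, 5 lost their call. The calls of these genes may therefore depend on the probe set.

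Of the 149 liver genes that passed at 1000 mg/kg, 105 were higher and 44 lower, and 58 changed at least 1.5-fold. With arrays centred on their medians the split was 70 higher and 57 lower, and with quantile normalization 80 higher and 62 lower. The count fell to 40 without 1000 mg/kg replicate 3, 82 without replicate 4 and 95 without replicate 1, and to 96 and 98 without control replicates 1 and 2. A fit of the 2 groups alone called 50 genes.

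**Figure D2:**
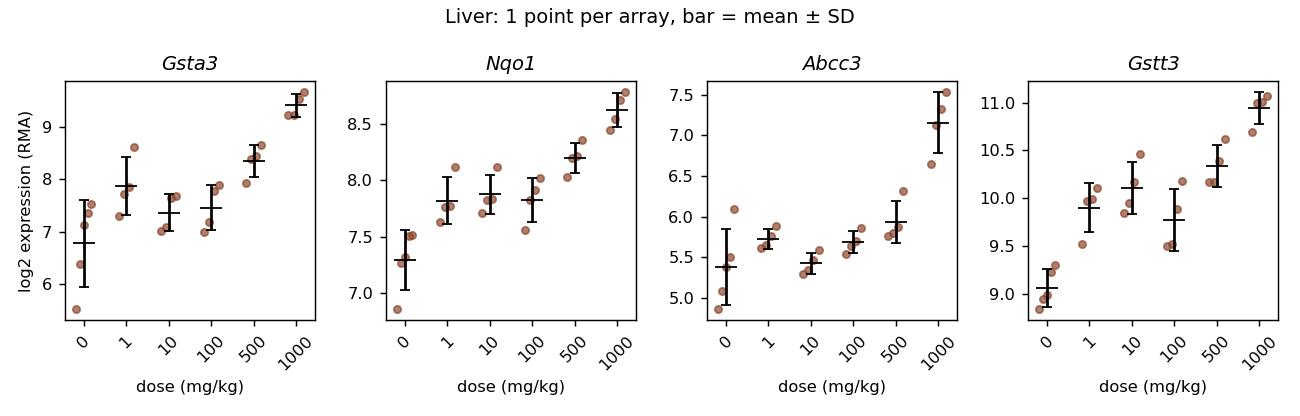
Log2 expression (y axis) of Gsta3, Nqo1, Abcc3 and Gstt3 in liver by dose in mg/kg (x axis), with 1 point per array and bars for mean ± SD. Group means at 1000 mg/kg were 9.42, 8.62, 7.16 and 10.94, against 6.77, 7.29, 5.39 and 9.06 at 0 mg/kg.

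Among the gene lists fixed in advance, camera at the preset correlation called 6 in liver at 1000 mg/kg, where other splits of the arrays gave up to 8. Of 19 measured genes of cholesterol synthesis, 11 rose, and 17 did when adjusted over the list alone. The list median was 0.68 on the log2 scale. Fdft1, squalene synthase, rose 1.60-fold, Mvk 1.54-fold, Ebp 1.45-fold and Tm7sf2 1.54-fold, although another probe set of Mvk gave -0.18. Of this list 1 gene passed without 1000 mg/kg replicate 3 and 1 in a fit of the 2 groups alone, and 7 without 1000 mg/kg replicate 4 or control replicate 2 or 4. Camera gave an adjusted p of 7.34e-22, and adjusted p = 0.171 with an estimated correlation. Of 21 targets of NRF2, the oxidant-responsive transcription factor, 6 rose and 1 fell, and 11 rose and 1 fell when adjusted over the list alone. The gene that fell was Hmox1, heme oxygenase 1 (log2 change -0.45, adjusted p = 0.0375), and no target fell without control replicate 3 or 5, without any 1 of the 4 arrays of 1000 mg/kg or in a fit of the 2 groups alone. The leading members of the list were Nqo1, Gsta3, Akr7a3 and Gsr, glutathione reductase, which rose 1.65-fold. The list had a camera adjusted p of 9.87e-11, and adjusted p = 0.0272 with an estimated correlation. Of 18 targets of the xenobiotic receptors CAR and PXR, 7 rose, and 9 rose and 1 fell when adjusted over the list alone. Abcc3, Gsta3, Ces2c and Cyp3a23-3a1, a cytochrome P450 that rose 1.79-fold, led this list. Gsta3 belongs to both this list and the NRF2 list. The NRF2 list as written does not hold this symbol, which entered it as the match of another name. Without 1000 mg/kg replicate 3, and in a fit of the 2 groups alone, 4 of the CAR and PXR targets rose, and 1 fell without control replicate 1, with brighter genes only, quantile normalization, centred arrays, a variance trend or array weights. By camera its adjusted p was 1.96e-09, and adjusted p = 0.0430 with an estimated correlation.

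Of 12 measured genes of the growth hormone and IGF axis, 5 fell in liver at 1000 mg/kg, and 5 fell and 1 rose when adjusted over the list alone. Serpina6, the corticosteroid carrier, changed by -0.72, Igfbp3 by -0.66, Ghr, the growth hormone receptor, by -0.42, and Igf1 by -0.28 on the log2 scale. The number that fell was 2 without 1000 mg/kg replicate 3, 3 without replicate 4 and 2 in a fit of the 2 groups alone. Camera gave an adjusted p of 9.50e-05, and adjusted p = 0.0195 with an estimated correlation. Of 29 cell cycle genes, 2 fell, Ccnd1 and Cdk1, and 7 fell when adjusted over the list alone. In a fit of the 2 groups alone 8 fell, and 1 of the 6 members among the brighter genes. Ccna2 and Ccnb2, mitotic cyclins, did not pass (adjusted p = 0.0574 and 0.0710). Liver replicate 3 of 500 mg/kg lay far above its group in Ccna2 (6.52, others 3.39 to 4.17) and Ccnb2 (7.53, others 4.93 to 5.12). In Cdk1 it lay at 7.71 (others 5.37 to 5.70). This array enters the spread shared by all doses, and a fit of the 2 groups alone leaves it out. Whether it alone moved the count was not tested. Ccnb2 had a log2 change of -1.67. Ccna2 lay at 4.48 in controls and at 2.73 at 1000 mg/kg, a level not shown to lie above background, so that the size of its change is not settled. The list had a camera adjusted p of 1.70e-09, and adjusted p = 0.495 with an estimated correlation. None of 12 macrophage and Kupffer cell markers passed, and 3 were lower when adjusted over the list alone. All 12 had a negative log2 change, with a median of -0.21. By camera its adjusted p was 9.50e-05, and adjusted p = 0.539 with an estimated correlation.

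Across all liver doses, 94 genes had a trend with dose rank, 74 rising and 20 falling. With arrays centred on their medians 43 rose and 29 fell, and with quantile normalization 51 rose and 27 fell. The count was 30 without 1000 mg/kg replicate 3, 45 without replicate 4, and 62 without 500 mg/kg replicate 4. Without control replicates 1, 4 and 2 it was 42, 52 and 60. Abcc3 was the 1 gene that differed between 1000 and 500 mg/kg. It was at 7.16 ± 0.38 (SD, n = 4) against 5.94 ± 0.26 (SD, n = 4), a log2 difference of 1.22 with a limma adjusted p of 0.0338. The count was 0 without 500 mg/kg replicate 3 or 4 or 1000 mg/kg replicate 2 or 3, 3 without 500 mg/kg replicate 1 or 1000 mg/kg replicate 1, and 14 without 1000 mg/kg replicate 4. In a fit of these 2 groups alone Abcc3 did not pass (adjusted p = 0.319). Of the 7 genes called at 500 mg/kg, 5 were also called at 1000 mg/kg, all higher at both doses. Independent lists of these sizes would share 0.0517 higher genes, and 100 simulated draws with no effect and the same controls shared at most 0. These draws leave out the effects, so they do not measure what the shared controls add to lists of 7 and 149 genes. With control replicates 1 to 3 used for 500 mg/kg and the rest for 1000 mg/kg, 3 genes were shared, and with replicates 4 and 5 used for 500 mg/kg, 1.

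In kidney no gene passed at 1, 10, 100 or 500 mg/kg with limma. Unadjusted p-values under 0.05 numbered 423, 1045, 971 and 722, and fits of the 2 groups alone called 0 genes at each of these doses. Without control replicate 5, 2 genes passed at 100 mg/kg. The cell cycle list had medians of -0.10, -0.15, -0.24 and -0.30 on the log2 scale at these doses, with camera adjusted p-values of 0.0107, 1.50e-05, 5.69e-12 and 8.63e-27. With an estimated correlation the call held at 500 mg/kg (adjusted p = 0.0322) and not at 1, 10 or 100 mg/kg (adjusted p = 0.582, 0.379 and 0.159 with an estimated correlation). No gene differed between 1000 and 500 mg/kg with limma, where 827 had an unadjusted p under 0.05, a fit of the 2 groups alone called 0, and 1 passed without 1000 mg/kg replicate 4. As no gene was called at 500 mg/kg, 0 calls were shared with 1000 mg/kg.

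Kidney expression of cell cycle genes fell at 1000 mg/kg. Ccna2, cyclin A2, fell from 5.65 ± 0.44 (SD, n = 5) to 3.67 ± 0.43 (SD, n = 4), a log2 change of -1.97 (limma adjusted p = 2.52e-05), with 1 array, replicate 3, as low as 3.11. The level of Ccna2 at 1000 mg/kg is not shown to lie above background, so that the size of its fall is not settled. Cdkn3 changed by -1.92, Cdk1 by -1.61, Ccnb2 by -1.61, the proliferation marker Mki67 by -1.54, the spindle proteins Prc1 and Kif20a by -1.53 and -1.42, and Cks2 by -1.38. Ptgs2, the inducible cyclooxygenase, fell from 6.57 ± 0.56 to 4.78 ± 0.35 (adjusted p = 0.000109), and Mfap4, of the extracellular matrix, changed by -1.39. The largest rise among the named genes was in Dmrtc1c1, 2.49-fold from 9.84 ± 0.44 to 11.15 ± 0.16 (adjusted p = 0.000341). Gtpbp4 rose 2.45-fold, although 1 of its 4 arrays, replicate 4, lay at 9.56 and the other 3 between 8.08 and 8.26. Gstm1, a glutathione transferase, rose 2.31-fold and Gsta3 1.88-fold. The tocopherol carrier Ttpa rose 1.94-fold, Bhmt, a homocysteine methyltransferase, 1.94-fold, Fam13c 1.84-fold, the sulfotransferase Sult1a1 1.78-fold, Cyp2e1, a cytochrome P450, 1.69-fold and Cracdl 1.64-fold. Gtpbp4, Ttpa and Fam13c have other probe sets, and their calls may depend on the probe set.

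In all, 220 kidney genes passed at 1000 mg/kg, 72 higher and 148 lower, and 86 of them changed at least 1.5-fold. With arrays centred on their medians the split turned to 138 higher and 107 lower, and with quantile normalization it was 100 higher and 134 lower. The count fell to 97 without 1000 mg/kg replicate 3, and to 128, 130 and 139 without control replicates 3, 2 and 4. It was 110 in a fit of the 2 groups alone. Markers of adipocytes varied among kidney arrays. Their mean lay more than 0.5 log2 units above the control mean in 1 control array, replicate 4 (0.86), and in 6 arrays of 1 to 500 mg/kg (0.83 to 2.26), whereas the 4 arrays of 1000 mg/kg lay between -0.48 and -0.20. Without the arrays above this limit 109 genes passed, and 100 of the 220 remained called.

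**Figure D3:**
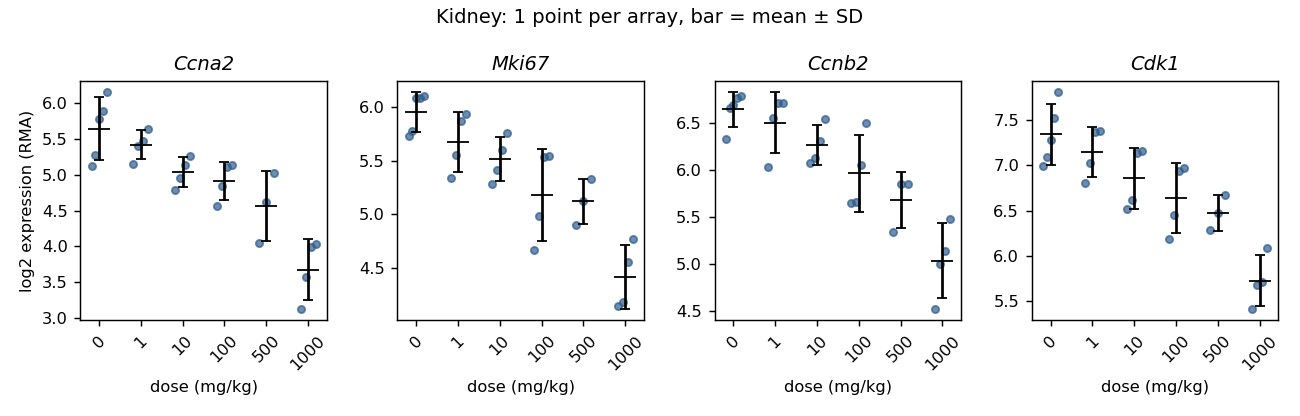
Log2 expression (y axis) of Ccna2, Mki67, Ccnb2 and Cdk1 in kidney by dose in mg/kg (x axis), with 1 point per array and bars for mean ± SD. Group means at 1000 mg/kg were 3.67, 4.41, 5.04 and 5.73, against 5.65, 5.96, 6.65 and 7.34 at 0 mg/kg.

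Of 29 cell cycle genes, 18 fell in kidney at 1000 mg/kg, and 24 fell when adjusted over the list alone. All 29 had a negative log2 change, with a median of -0.53. Camera gave an adjusted p of 7.18e-35, and adjusted p = 0.0159 with an estimated correlation. With the adipocyte marker level as a covariate 16 of the 29 genes passed, and without the arrays high in these markers 15. Among the brighter genes only 9 of the list were tested, and 5 fell. The other 7 lists called by camera were not called with an estimated correlation. Of 42 targets of PPAR alpha, a regulator of fatty acid oxidation, 6 rose, and 13 did when adjusted over the list alone. They included Ehhadh (1.63-fold), Decr1 (1.44-fold), Cyp4a3 (1.32-fold) and Acadm (1.21-fold), and 2 of the list passed without the arrays high in adipocyte markers or in a fit of the 2 groups alone, and 3 without 1000 mg/kg replicate 3. The list had a camera adjusted p of 1.59e-07, and adjusted p = 0.159 with an estimated correlation. Of 22 genes of amino acid and urea metabolism, 3 rose, Hgd (1.36-fold), Gnmt (1.36-fold) and Bhmt, and 6 did when adjusted over the list alone. None passed without control replicate 2 or 3 or 1000 mg/kg replicate 3, and 1 passed without control replicate 4, without 1000 mg/kg replicate 2, without the arrays high in adipocyte markers or in a fit of the 2 groups alone. By camera its adjusted p was 0.000149, and adjusted p = 0.0533 with an estimated correlation. Of 18 CAR and PXR targets, 2 rose, Gstm1 and Gsta3, and 4 did when adjusted over the list alone. The list median was 0.01 and its mean 0.18. Camera gave an adjusted p of 0.00733, and adjusted p = 0.127 with an estimated correlation.

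Of 25 inflammation genes, 2 fell in kidney, Ptgs2 and Tnfaip3 (log2 change -0.53), and the same number did when adjusted over the list alone. None of the 5 members among the brighter genes passed. The list had a camera adjusted p of 0.0188, and adjusted p = 0.451 with an estimated correlation. Of 12 macrophage markers, 1 fell, Adgre1 (log2 change -0.80), and 2 did when adjusted over the list alone. This count was 0 without control replicate 2, without 1000 mg/kg replicate 2 or 3 or in a fit of the 2 groups alone, and 2 without control replicate 5, and none of the 5 members among the brighter genes passed. By camera its adjusted p was 0.0188, and adjusted p = 0.388 with an estimated correlation. Of 23 markers of the proximal tubule, 1 rose, Cyp2e1, also when adjusted over the list alone. It did not pass without control replicate 1, 2 or 4, without 1000 mg/kg replicate 2 or 3, or without the arrays high in adipocyte markers. Camera gave an adjusted p of 0.0467, and adjusted p = 0.409 with an estimated correlation. None of 11 endothelial markers passed, and 1, lower, did when adjusted over the list alone or without the arrays high in adipocyte markers. The list had a camera adjusted p of 0.0467, and adjusted p = 0.403 with an estimated correlation. Without control replicate 2 or 1000 mg/kg replicate 3, 4 kidney lists passed in place of 8. The inflammation, proximal tubule, macrophage and endothelial lists were the ones that lost their call when 1 array was left out.

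Across kidney doses, 198 genes had a trend with dose rank, 51 rising and 147 falling. With arrays centred on their medians 107 rose and 105 fell. Without the arrays high in adipocyte markers 102 genes passed, and without 1000 mg/kg replicates 1 and 3 the counts were 129 and 115.

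**Figure D4:**
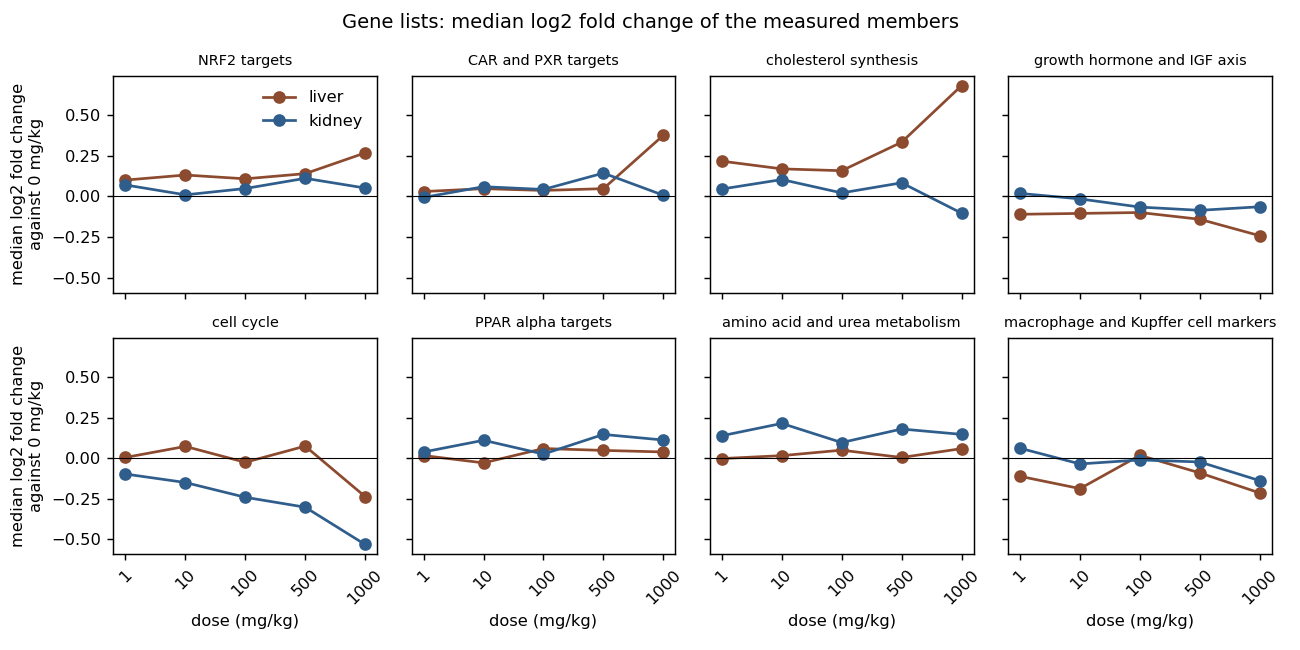
Median log2 fold change against 0 mg/kg (y axis) of the measured members of 8 gene lists, by dose in mg/kg (x axis), in liver and kidney. At 1000 mg/kg the cholesterol synthesis median was 0.68 in liver and -0.10 in kidney, and the cell cycle median was -0.24 in liver and -0.53 in kidney.

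The responses of liver and kidney to 1000 mg/kg were compared gene by gene. Gstt3, Abcc3, Adh7 and Gsta3 had the higher log2 change in liver, by 1.68, 1.58, 1.60 and 1.74 (limma adjusted p = 3.96e-08, 2.04e-05, 0.00387 and 0.0177). In kidney Gstt3 had a log2 change of 0.20, Abcc3 of 0.20 and Adh7 of -0.11, with adjusted p-values of 0.136, 0.293 and 0.797. Ptgs2 fell in kidney and had a log2 change of 0.08 in liver, a difference of 1.87 (adjusted p = 0.000176). Ptgs2 lay at 3.13 in liver controls and Adh7 at 3.27 in kidney controls, and without detection calls these levels are not shown to lie above background. Lower responses in liver were found for Aldh1b1 (-2.25), Ccnd1 (-1.47), Sit1 (-1.30), Apoa4 (-1.30) and Slc25a34 (-1.25). Their limma adjusted p-values were 0.0492, 0.0163, 0.0487, 0.0163 and 0.0239. Sit1 and Slc25a34 passed in neither organ, with log2 changes of -0.47 and -0.50 in liver and 0.83 and 0.75 in kidney. Aldh1b1, Ccnd1 and Apoa4 fell in liver and did not pass in kidney. Slc25a34 lay at 4.11 in liver controls and Apoa4 at 3.93 in kidney controls, also not shown to lie above background. Cdk1 and Cdkn3 had differences of -0.36 and -0.24 between the organs (adjusted p = 0.786 and 0.911). In all 89 genes differed, 62 with the higher response in liver and 27 with the lower. With arrays centred on their medians these were 26 and 41, and with quantile normalization 41 and 33. The count was 34 and 55 without liver 1000 mg/kg replicates 3 and 4, 59 without liver control replicate 1, 48 and 52 without kidney 1000 mg/kg replicates 1 and 2, and 58 and 57 without kidney control replicates 1 and 2. It was 59 with the mean of all probe sets of a gene.

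Both organs called 7 genes at 1000 mg/kg, where independent lists of 149 and 220 genes would share 2.31 (Fisher's exact test, two-sided, p = 0.00851). The test treats the arrays of the organs as unrelated, and the labels do not say which liver and kidney came from the same rat. Gsta3 and Aldh1l1, a folate enzyme, were higher in both. Cdk1, Cdkn3, Nrep and Slpi were lower in both. Pacs2 was higher in liver and lower in kidney.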

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

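The tests of fat tissue, of stromal cells or macrophages and of a control group that stands apart, given for the kidney, were chosen after the result was seen.

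Among the named genes and described lists, 218 groups of 4 or 5 arrays were examined for an array far from the others, and 14 held one, where chance gives about 1 in 20 groups, or 10.9. In liver controls these were Cidea in replicate 1 (6.52, others 7.43 to 7.67), Acat2 in replicate 2 (8.19, others 8.89 to 9.17), Slpi in replicate 3 (9.69, others 9.02 to 9.19), Ccna2 in replicate 3 (5.00, others 4.29 to 4.46) and Serpina6 in replicate 4 (12.61, others 12.41 to 12.44). At 1000 mg/kg in liver they were Mvk (9.42, others at most 9.05) and Igf1 (12.93, others 12.97 to 12.97) in replicate 3, and the mean of the growth hormone and IGF list in replicate 2 (0.0405 over controls, others -0.26 to -0.23). In kidney controls they were Ccnb2 (6.33, others 6.66 to 6.80) and the mean of the PPAR alpha list (-0.0808, others 0.01 to 0.03) in replicate 5. At 1000 mg/kg in kidney they were Gtpbp4 in replicate 4 (9.56, others 8.08 to 8.26), Cdkn3 (4.68, others 5.50 to 5.53) and Hgd (11.36, others at most 11.04) in replicate 3, and the mean of the amino acid and urea list in replicate 1 (0.19, others 0.23 to 0.23).

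The response to 1000 mg/kg differed between the organs for 89 genes by the limma contrast of the responses. Only 1 of 100 splits, the real one, gave as many, which passes the limit set in advance, but the highest of the others gave 81. The splits shuffled the arrays of each organ separately, so they keep no match between liver and kidney arrays of a rat. Chance is therefore not firmly excluded. Named genes with a higher response in liver were Ptgs2 (1.87), Gsta3 (1.74), Gstt3 (1.68), Adh7 (1.60), Abcc3 (1.58), Cks2 (1.48), Acsm2 (1.47), Acat2 (1.28), Ces2c (1.27), Akr7a3 (1.04), Nqo1 (0.93), Tnfaip3 (0.85), Cyp3a23-3a1 (0.83), Mvk (0.65) and Ebp (0.49), as liver minus kidney log2 fold changes. Those with a lower response in liver were Aldh1b1 (-2.25), Ccnd1 (-1.47), Sit1 (-1.30), Apoa4 (-1.30), Slc25a34 (-1.25), Dmrtc1c1 (-1.12), Cracdl (-1.05), Klrg1 (-1.03), Gstm1 (-1.02), Nrcam (-1.01) and Acadm (-0.38). Control levels were low for Ptgs2 (3.13) and Dmrtc1c1 (3.18) in liver and for Adh7 (3.27), Cyp3a23-3a1 (2.97), Nrcam (3.65) and Apoa4 (3.93) in kidney, and without detection calls a smaller response there is not shown.

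Of 10216 probe sets without a single gene symbol, 3 were called at 1000 mg/kg in liver and 15 in kidney, with limma and adjustment over these probe sets.

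Cell cycle genes were lower in kidney at 1000 mg/kg, with a median of -0.53. Fat tissue in the sample is argued against, since the median was -0.54 with the adipocyte marker level as a covariate. A general loss of macrophages, endothelial cells or fibroblasts is argued against as the whole cause. The medians of their lists lay 0.39, 0.40 and 0.42 above that of the cell cycle list, with SDs of 0.25, 0.12 and 0.33 over their members. Adgre1 (-0.80), Mfap4 (-1.39) and, below the threshold, 4 of the 15 fibroblast markers, Lum (-0.91), Postn (-0.80), Col1a1 (-0.72) and Col3a1 (-0.65), go with such a loss, so that a part stays open. Lymphocytes and neutrophils were not part of this test, and list medians cannot show the loss of a small subset of cells. A control group that stands apart is argued against as the whole cause, since the mean level fell with dose rank among the 15 arrays of 1 to 500 mg/kg alone (Spearman's rho = -0.73, permutation p = 0.00301; Pearson's r = -0.71, permutation p = 0.00319). Among these 15 arrays the 3 of 500 mg/kg tie as farthest from the median rank. Without replicates 1 and 2 of that dose, left out by their order alone, r was -0.64. Over all 24 arrays rho was -0.88 and r -0.88 (both permutation p = 1e-05, the smallest the permutations can give). Adjusted over the sets of 15 and 24 arrays, the permutation p-values were 0.00301 and 2e-05 for rho and 0.00319 and 2e-05 for r. A response of proliferation to dose may remain as a hypothesis.

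In liver, 9.45%, 9.22% and 9.18% of genes had an unadjusted p under 0.05 at 1, 10 and 100 mg/kg. If the control arrays stood apart, contrasts without them would hold few such genes, and the 3 contrasts among these doses held 3.50%, 3.81% and 3.59% (median 3.59%). A response that continues to higher doses remains open, since the 45.6% of these genes with the same sign in 1000 minus 500 mg/kg lay within 100 reassignments of residual arrays (22.5% to 69.7%), and the bound set in advance, which took this as evidence against, was wrong because so wide a range separates neither case. Different value distributions remain open too, since the mean share was 9.28% and became 7.69% with quantile normalization. Control arrays that stand apart are consistent with these values, but a response that is complete at 1 mg/kg would give them too and is untested.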

How the results depend on the processing

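The alternatives for fat tissue and for dose and number as a random block were chosen after the data were seen. The cause of a moved count was not tested, except that fewer arrays or genes enter some fits. In liver at 500 mg/kg (7 genes) the counts were 11 with the mean of probe sets, 67 with brighter genes only, 3 with quantile normalization, 3 with centred arrays, 53 with a variance trend, 20 with array weights and 1 in a fit of the 2 groups. At 1000 mg/kg in liver (149) they were 270 with brighter genes only, 225 with array weights and 50 in a fit of the 2 groups, and the trend count (94) became 222 with brighter genes only and 145 with a variance trend. In liver the fit of the 2 groups gave 0 at 10 mg/kg (1) and 1 at 100 mg/kg (0). Between 1000 and 500 mg/kg in liver (1) the counts were 2 with the mean of probe sets, 14 with brighter genes only, 7 with centred arrays and 10 with a variance trend. In kidney at 1000 mg/kg (220) the fit of the 2 groups gave 110, and without arrays high in adipocyte markers 109. The kidney trend (198) became 111 with brighter genes only and 102 without those arrays, and 10 mg/kg (0) became 1 without them. The organs' difference (89) became 59 with the mean of probe sets. With an estimated correlation 3 liver lists (6) and 1 kidney list (8) passed, and with fry 3 kidney lists. Over both organs fry ended the call of 7 of 14 lists, and brighter genes only of 3. Array weights, centred arrays, quantile normalization, the replicate block and leaving out kidney arrays high in adipocyte markers each ended 1. With brighter genes only, 40 liver calls (5) were shared by 500 and 1000 mg/kg, and 12 (7) by the organs. Of results from other probe sets of named genes, 12 kept their call or lack of one and 5 lost it. For Mvk in liver 1 changed direction (-0.18).

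Across doses, arrays of a replicate number share only that number. Deviations of same-numbered arrays of other doses correlated at -0.01 in liver and 0.05 in kidney on average. With a replicate block the counts were 0 (1) in liver at 10 mg/kg, 3 (7) at 500 mg/kg, 1 (0) in kidney at 100 mg/kg, 361 (220) in kidney at 1000 mg/kg and 3 (5) for the liver calls shared by doses. Within lists it gave 3 (5) lower growth hormone and IGF genes and 0 (1) lower NRF2 targets in liver, and in kidney 0 (1) lower macrophage markers, so that Adgre1 did not pass, and 2 (1) higher proximal tubule markers. The counts at 1000 mg/kg in liver (103) and of the organs' difference (81) stayed within 1.5 times. Only the controls hold a replicate 5, so within an organ the block takes that array out of the contrasts. Leaving out that array alone gave 329 genes in kidney and 137 in liver at 1000 mg/kg. So the other numbers alone do not explain the moves with the block. Liver and kidney arrays of a dose with the same number correlated at 0.10 on average over all genes, with 13 of 24 pairs over 0.1 and 21 kidney arrays matching the liver array of their number best. Over the 200 most variable genes they correlated at -0.08 to 0.56, with a mean of 0.38. There 23 of 24 pairs lay over 0.1, and 23 kidney arrays matched best the liver array of their number, out of 4 or 5. The labels do not pair the organs and some pairs lay under 0.1, so the numbers were not taken as pairs. Though from the data, not the design, the matching points to organs of the same rats. The main comparisons treat the organs' arrays as unrelated, which may not hold. With dose and number as a random block 112 genes differed between the organs.

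Leaving out 1 array at a time gave ranges of 0 to 0 at 1 mg/kg, 0 to 2 at 10, 0 to 0 at 100, 2 to 14 at 500 and 40 to 137 at 1000 mg/kg in liver, 30 to 123 for its trend, 0 to 14 between 1000 and 500 mg/kg and 6 to 7 lists. In kidney they were 0 to 0 at 1, 10 and 500 mg/kg, 0 to 2 at 100, 97 to 329 at 1000 mg/kg, 115 to 263 for the trend, 0 to 1 between 1000 and 500 mg/kg and 4 to 10 lists. For the organs' difference they were 34 to 108. Of 96 named gene results, which include some not called in the main fit, 35 lost their call without some single array. Results not called cannot lose a call, so the share of calls lost is above 35 of 96. In the leave-one-out fit with the largest adjusted p for each result, all kept their direction. A fit of the 2 groups alone ended 24 calls of named genes, and the replicate block 13.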

Other observations

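The test of the neighbours of Gstt3 was chosen after the result was seen. Several lists of toxicological interest did not pass in either organ at 1000 mg/kg. The targets of AhR had medians of 0.05 in liver (camera adjusted p = 0.238) and -0.07 in kidney (adjusted p = 0.420), where the mean was 0.32 and camera's direction upward. Cyp1a1, a cytochrome P450, had a log2 change of 2.12 in kidney (SE 0.74), which did not pass (limma adjusted p = 0.186). Nqo1, in the liver, was the 1 called AhR target. The kidney injury markers had a median of -0.05 in kidney, and 0 of 23 were called with limma. The camera adjusted p of this list was 0.974, with camera's direction upward. The p53 and DNA damage genes had medians of -0.04 in liver (adjusted p = 0.677) and -0.08 in kidney (adjusted p = 0.0980). The stellate cell and fibroblast markers had a median of -0.11 in kidney (adjusted p = 0.0533), and the adipocyte markers one of -0.16 (adjusted p = 0.974).

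Gstt3 in liver lay between 8.83 and 9.30 in the control arrays and between 9.49 and 11.07 in all 20 dosed arrays. Its log2 change was 0.84, 1.04, 0.71, 1.28 and 1.88 from the lowest to the highest dose. Of the 5 measured genes on each side of it in the GRCr8 gene order, Gstt1 and Mif were also called at 1000 mg/kg in liver, with log2 changes of 0.53 (adjusted p = 0.00643) and 0.44 (adjusted p = 0.0395). Mif had a log2 change of 0.47 at 1 mg/kg, and Gstt3 in kidney one of 0.20 at 1000 mg/kg (adjusted p = 0.136).

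Other splits of the same arrays gave counts as large as the real one for some results and not for others. Chance can be excluded at this level for the liver counts of 7 genes at 500 mg/kg, 149 at 1000 mg/kg and 94 with a trend, where 1 of 100 splits, the real one, reached the count and the highest others were 2, 26 and 2. The same holds for kidney counts of 220 at 1000 mg/kg and 198 with a trend (1 of 100, highest others 52 and 5). For the 8 kidney lists 4 of 100 splits, the real one included, reached the count, and the highest other was 9. This passes the limit set in advance, but another split called more lists, so chance is not firmly excluded. The split counts are not adjusted for the number of results tested. Chance cannot be excluded for the 6 liver lists (28 of 100 splits, highest other 8), the liver call at 10 mg/kg (5 of 100, highest other 1) or the liver call between 1000 and 500 mg/kg (2 of 35, highest other 1). For counts of 0 the splits decide nothing, since every split reaches 0: 100 of 100 for liver at 1 and 100 mg/kg (highest others 3 and 1) and for kidney at 1, 10 and 100 mg/kg (17, 1 and 9), 56 of 56 for kidney at 500 mg/kg (1) and 35 of 35 for kidney between 1000 and 500 mg/kg (5).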
